A study of Pimephales promelas with 28 samples.

How the data were processed

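Gene expression was measured in liver, gill and brain of adult male fathead minnows (Pimephales promelas) with 28 2-colour oligonucleotide arrays. Fish had been exposed for 96 h in water to titanium dioxide nanoparticles at 1 mg/L (low dose) or 10 mg/L (high dose), or left unexposed (0 mg/L). Per the labels, the RNA of a tissue sample was labelled with Cy5 and a common reference of male and female liver, gonad and brain RNA with Cy3, on every array, so dye effects were not balanced by swaps. Gill and liver had 4 arrays in each of the 3 dose groups, which the series design calls biological replicates. Brain had 1 array of control, 1 array of the low dose, both labelled as pooled, and 2 arrays of the high dose. Whether these last 2 arrays came from separate fish is not given in the sources used here.

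Per the labels, total RNA was extracted with Qiagen RNeasy Plus columns and amplified with the Agilent Low-RNA Input Linear Amplification Kit. Per the file headers, images were read with Agilent Feature Extraction 9.1.3.1. The deposited scanner files hold intensity values, which are the mean brightness of each spot in each dye and the median of its local background on a linear scale. They also hold the log10 ratio of Cy5 over Cy3 that Feature Extraction computed after background subtraction, spatial detrending and LOWESS dye normalization, per the file headers. The authors' deposited value table holds log2 ratios. On bright unflagged spots, with at least 2000 units of signal in both dyes, its columns matched the scanner's processed log2 ratio of Cy3 over Cy5 with slopes of 0.996 to 1.01 and correlations across spots of 0.999 to 1.00, so its sign is opposite to the one used here. Its column medians ran from -0.0106 to -0.000652. The treatment of dim spots in that table is not given in the sources used here.

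Ratios were recomputed from the intensities with limma 3.58.1 in R 4.3.3. Background was corrected with normexp at an offset of 50, and dyes were normalised by loess within each array, with control spots and spots that the scanner software marked as outliers given weight 0. Those spots were then left out, and spots of a probe were averaged, which gave 21495 probes. All values are log2 of sample over reference. A probe was tested where its Cy5 signal was well above background, as the scanner software called it, on at least 4 arrays of the fit. Linear models with a moderated variance that follows mean intensity were fitted to the 12 gill arrays, to the 12 liver arrays, and to all 28 arrays for brain, for gill against liver and for the difference between tissues in the response. The last of these fits assumes that a lone brain array varied like the arrays of the other groups. Probes were called at a Benjamini-Hochberg adjusted p of at most 0.05. For a probe that was not well above background on any array of 1 group, the test is given and no fold. Lower bounds computed from Cy5 alone are open to dye bias, and for alpha-amylase and the leading unnamed probes higher in gill they exceeded the fold of the mean ratios, so they were not used.

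The number of probes well above background in Cy5 was 11103 to 12751 on brain arrays, 6773 to 11835 on gill arrays and 7255 to 10758 on liver arrays. The number of arrays limits the precision of every comparison. The procedure was tested on simulated data with the spread of these arrays, 200 changed probes per run and 5 runs. For gill at high dose it recovered 38% of changes of 1.5-fold, 69.2% of 2-fold, 90.4% of 3-fold and 96.4% of 4-fold. For liver at high dose the shares were 28.8%, 69.2%, 86% and 92.8% for the same 4 sizes. Of all calls in the simulations, 4.42% were false in gill and 6.23% in liver. These recovered shares hold for 200 changed probes. Where fewer probes change, the adjustment of p is stricter and a lower share would be recovered. The shares therefore do not give the size of change that a comparison without calls excludes.

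The files name 33 of the 21495 probes by a gene, and these names were read by hand. The assignment of those names to genes was written after values had been looked at. The remaining probes have IDs that the files do not pair with gene names. Names of 6937 probes hold a GenBank identifier. Of these identifiers, 0 were found among the RefSeq identifiers, a separate series, in the reference table of this species. The other names and the probe sequences were not compared with that table, so the genes may still be in it. Of 27 lists of pathway genes and cell markers, 18 had no named probe, 8 had 1 or 2 and 1 had 3, so tests of lists were not possible. The genes chosen for reporting whatever their values (cyp1a, metallothionein, hmox1, hsp70, sod1, catalase, vitellogenin and pcna) were not among the named probes and were not analysed here. The rule for named genes took up to 12 each way among those that passed in each gill and liver comparison of a dose with control, or, where fewer than 10 passed, those and then the named genes with the smallest p up to 10. It took up to 6 each way for brain and for the difference between tissues, up to 10 each way for gill against liver and up to 5 each way of those passing for high against low dose. Named genes given for high against low dose did not pass and were added to the rule after the data were seen. Unnamed probes are given by ID, at most 2 higher and 2 lower per comparison.

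The comparisons, the model for single probes, the gene lists and most alternatives were fixed before the data were examined. The alternatives were no background subtraction, the scanner's own ratio, median centring, quantile scaling of average intensities, the authors' value table, no filter and a stricter filter on dim probes, array weights, the replicate number as a block, other sets of arrays in the fit, and each array left out in turn. A block for the slide was not run, because each slide held 1 array. Scan day, of which the file headers give 3, was added as a block and as within-day fits after the data were seen, as were fits without doubted arrays or probes, with the brain high dose arrays averaged, and with alpha-amylase as a covariate. Day 1 held too few arrays of gill or liver for a fit of its own. Day 2 held 2 control, 1 low dose and 1 high dose array of gill and 1, 2 and 2 of liver, and day 3 held 2, 2 and 2 of gill and 2, 1 and 1 of liver. Within a day, a group of 1 array was assumed to vary like the others, and calls that rest on it describe that array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.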

Results

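The series asked how titanium dioxide nanoparticles, particles of a white pigment, in the water altered gene expression in liver, gill and brain of adult male fathead minnow, a small freshwater fish used in toxicity testing. Gill is the tissue in direct contact with the water, and liver is the main organ of detoxification. There were 4 arrays for each of control, 1 mg/L and 10 mg/L in gill and in liver, and 1, 1 and 2 arrays in brain. Signals of the common reference correlated across probes at r = 0.968 to 0.998 between arrays of different tissues, whereas sample signals correlated at 0.628 to 0.911 between tissues. Replicate arrays of a gill group correlated at 0.899 or more in their log2 ratios and those of a liver group at 0.886 to 0.934 (across probes, which are not independent replicates). Log2 values are sample over reference, opposite in sign to the authors' value table.

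Gill and liver of control fish were compared first, as a yardstick for the size of other differences. Complement C3-S, a form of the central protein of the complement cascade, which is secreted by liver, was 148-fold lower in gill than in liver. Alpha-amylase, a starch-digesting enzyme typical of the pancreas, was lower in gill, where it was not well above background on any of the 4 control arrays, so that no exact fold is given. Zona pellucida glycoprotein 3, an egg envelope protein, was 2.47-fold lower in gill than in liver and far below the reference in both tissues. CD18 type 2, an integrin subunit of white blood cells, was 1.18-fold lower in gill. Cadherin 17, an adhesion protein, passed the test as lower in gill, but it was not well above background on any gill control array and on only 2 of the 4 liver control arrays, so no fold is given.

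The log2 difference, gill minus liver with 4 arrays each, was -7.21 (SE 0.311, limma adjusted p = 1.24e-14) for complement C3-S, with mean log2 ratios of -4.89 ± 0.13 (SD) in gill and 2.32 ± 0.65 in liver. Alpha-amylase passed with a limma adjusted p of 5.39e-09 and had a mean log2 ratio of 7.27 ± 2.02 in liver, and cadherin 17 passed with a limma adjusted p of 0.0357. The difference was -1.30 (SE 0.306, limma adjusted p = 0.00147) for zona pellucida glycoprotein 3 and -0.24 (SE 0.085, limma adjusted p = 0.0313) for CD18 type 2. Of 14 named genes tested, these 5 passed, and the same number passed adjusted over the list alone. The 9 others did not pass, among them cyclin B1, a mitotic cyclin (0.11, SE 0.186, adjusted p = 0.688), the taurine transporter (0.15, SE 0.212, adjusted p = 0.624) and cytochrome b, a mitochondrially encoded subunit of the respiratory chain (-0.45, SE 0.238, adjusted p = 0.146). With scan day as a block, within day 2 and within day 3, complement C3-S was at -7.21, -6.56 and -7.36 and zona pellucida glycoprotein 3 at -1.16, -1.05 and -1.31, and alpha-amylase passed in each (limma adjusted p = 3.52e-08, 9.50e-05 and 0.000363). CD18 type 2 and cadherin 17 lost their calls under several alternatives. For instance, the adjusted p of CD18 type 2 was 0.144 with median centring and that of cadherin 17 was 0.124 with the scanner's own ratios.

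Among all 13613 probes tested, 5381 differed between gill and liver of control fish, 3177 higher in gill and 2204 lower, and 952 of them by over 4-fold. The files do not pair the leading probes with gene names. EA_Pp_57709 (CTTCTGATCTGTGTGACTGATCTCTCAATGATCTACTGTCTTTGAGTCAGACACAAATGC) was higher in gill (limma adjusted p = 1.26e-17), and so was EA_Pp_62685 (limma adjusted p = 0.000199), and neither was well above background on any of the 4 liver control arrays. EA_Pp_51328 (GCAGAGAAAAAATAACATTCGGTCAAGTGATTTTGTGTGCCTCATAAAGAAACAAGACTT) was lower in gill by a log2 difference of -12.20 (limma adjusted p = 2.49e-18), and EA_Pp_66378 by -10.67 (limma adjusted p = 2.59e-14). Median centring moved the median of all probes by 0.29 towards gill and gave 5663 higher and 1238 lower. Blocked by scan day, 5770 probes passed, and within days 2 and 3 there were 1935 and 3616, the former with 1 liver array, while the stricter filter on dim probes, which tested fewer, gave 2638.

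**Figure D1:**
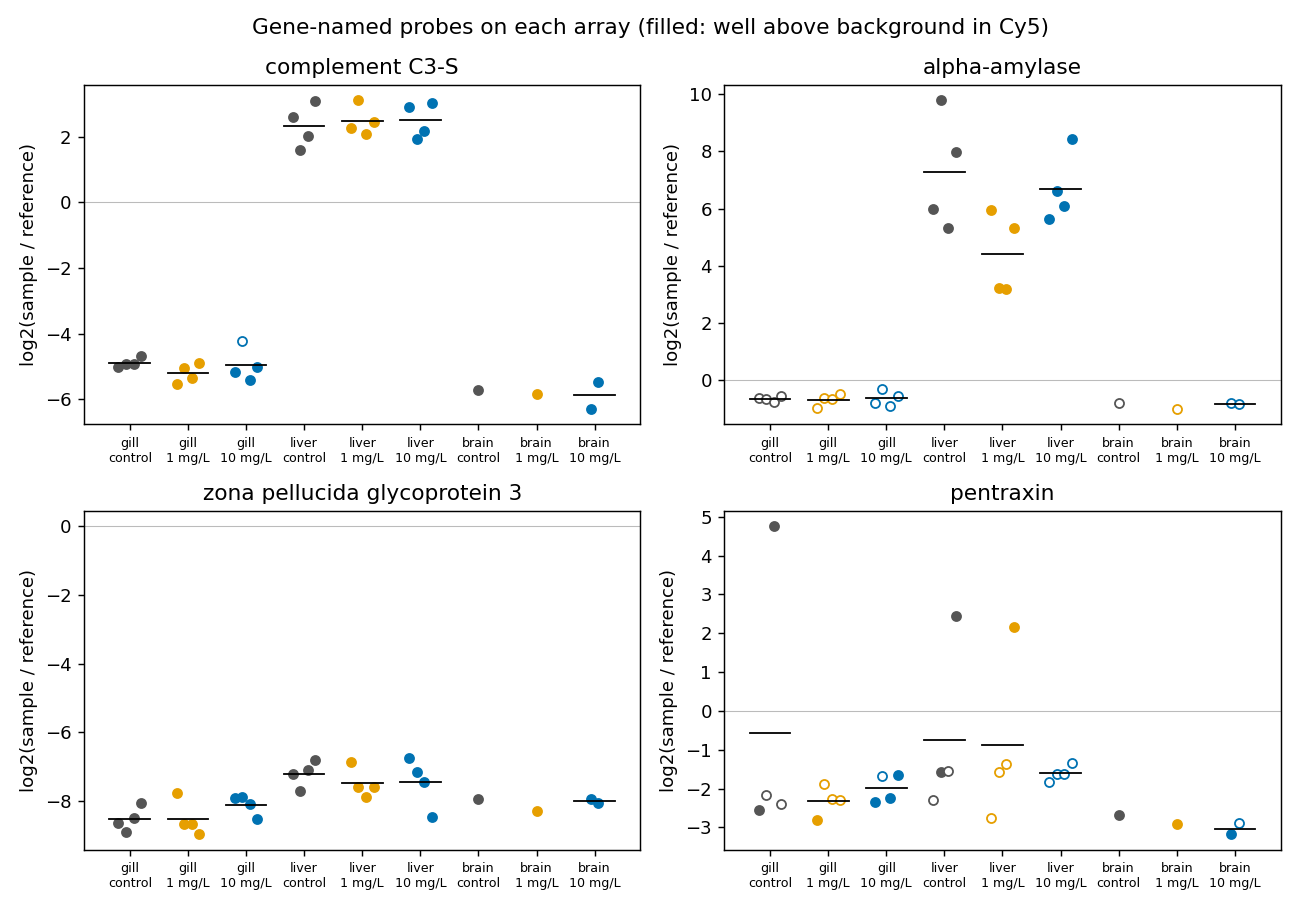
Each point is the log2 ratio of sample to reference of 1 gene-named probe on 1 array (vertical axis), by tissue and dose (horizontal axis), filled where the probe was well above background and open where not, and lines are group means. Complement C3-S was at 1.60 or more on the 12 liver arrays and at -4.23 or less on the others, and alpha-amylase reached 9.79 in liver and ranged 96.0-fold there.

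In gill at the high dose, none of the 10 named genes tested passed. Zona pellucida glycoprotein 3 had a log2 difference from control of 0.42 (SE 0.255, adjusted p = 0.554), and -0.03 within day 3. Within day 2 the 1 high dose array stood at -7.89, above the control arrays at -8.63 and -8.89. Myoblast determination protein, a transcription factor of muscle, was not well above background on any gill control array and did not pass (adjusted p = 0.52). Of the acute phase and complement list, complement C3-S had -0.07 (SE 0.228, adjusted p = 0.936) and pentraxin, a secreted pattern-recognition protein, had -1.40 (SE 1.28, adjusted p = 0.726). The other 6 were cytochrome b at -0.21 (0.43 within day 2), cyclin B1 at -0.09, CD18 type 2 at -0.04, the nuclear envelope protein lamin B1 at -0.04, the taurine transporter at 0.07 and follistatin, which binds activin, at 0.02. Pentraxin lay at 4.76 on gill control array 3 and at -2.54 to -2.15 on the other control arrays, and without array 3 its difference was 0.38.

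Across the array, limma called 0 of 10529 probes in gill at the high dose against control, with a smallest adjusted p of 0.0572. At an unadjusted p under 0.05 there were 1297 probes, 588 higher and 709 lower, where chance gives 526. The median SE was 0.164, and the median 95% interval reached 1.28-fold either way. With scan day as a block 0 probes passed and 1527 had an unadjusted p under 0.05, and within days 2 and 3 the counts were 0 and 0, with 804 and 854, where day 2 held only 1 high dose array (array 2) and its 2 controls included array 1. The stricter filter on dim probes gave 10 calls (2 higher and 8 lower), and the fit to all 28 arrays gave 53 (18 higher and 35 lower). No background subtraction and the scanner's own ratios gave 1 call each, as did leaving out gill control array 2, high dose array 1 or high dose array 4.

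Gill control array 1 carried brain signal, estimated at 14.8% from probes that are high in brain and low in gill, and 52 of the 53 such probes were well above background there. Gill high dose array 2 had the fewest probes well above background, at 6773. Without both arrays, 1 probe was called in gill at the high dose and 1147 had an unadjusted p under 0.05.

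**Figure D2:**
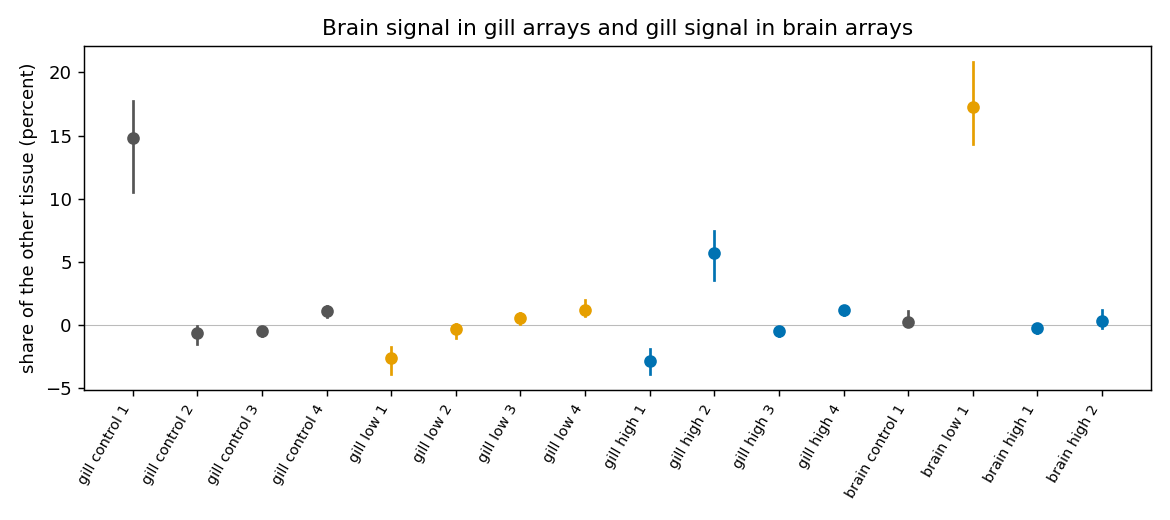
The vertical axis is the share in percent of brain signal in each gill array and of gill signal in each brain array (horizontal axis), as the median over probes specific to the other tissue, with a line from the first to the third quartile. Gill control array 1 stood at 14.8% and the brain low dose array at 17.3%, and the other arrays shown lay between -2.83% and 5.69%.

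In gill at the low dose, none of the 10 named genes tested passed either. The values nearest to a call were cyclin B1 at -0.30 (SE 0.211), complement C3-S at -0.32 (SE 0.228) and pentraxin at -1.74 (SE 1.28), each with an adjusted p of 1.00. Without gill control array 3 the difference of pentraxin was 0.04. Of the 7 others, myoblast determination protein was not well above background on any gill control array, and 6 lay between -0.03 for CD18 type 2 and 0.11 for cytochrome b. limma called 0 of 10529 probes, with 357 at an unadjusted p under 0.05, below the 526 that chance gives, and a smallest adjusted p of 0.0649. A scan-day block left 0 calls (417 at an unadjusted p under 0.05), and within days 2 and 3 the counts were 0 and 0 (307 and 455), with 1 low dose array on day 2. No background subtraction gave 1 call, and so did leaving out low dose array 3.

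Between the doses in gill, none of the 10 named genes tested passed. Zona pellucida glycoprotein 3 was nearest at 0.42 for high minus low dose (SE 0.255, adjusted p = 0.644), and cytochrome b was next at -0.32 (SE 0.239, adjusted p = 0.714). limma called 0 of 10529 probes, with 1015 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0764. Scan day in the model left 0 calls (1128 at an unadjusted p under 0.05), and within days 2 and 3 the counts were 0 and 0 (831 and 505), where day 2 set 1 array against 1. Without gill control array 1 and gill high dose array 2 there were 3 calls, all higher at the high dose. The fit to all 28 arrays gave 2, array weights gave 3, the stricter filter gave 1, leaving out high dose array 2 gave 2, and leaving out control array 3, low dose array 2 or low dose array 4 gave 1 each.

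**Figure D3:**
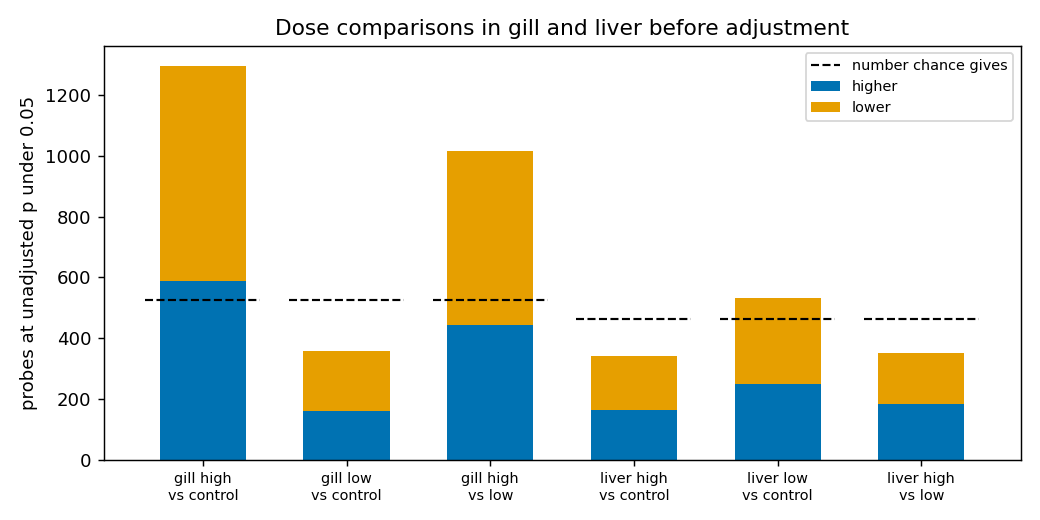
Bars give the number of probes at an unadjusted p under 0.05 (vertical axis) in each dose comparison of gill and liver (horizontal axis), split into probes higher and lower in the group named first, and dashed lines give the number that chance gives. The high dose in gill reached 1297 probes against control and 1015 against the low dose, where chance gives 526, and the 4 other comparisons had 340 to 531.

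In liver at the high dose, none of the 9 named genes tested passed. The taurine transporter had a log2 difference from control of -0.43 (SE 0.232, adjusted p = 0.995). Zona pellucida glycoprotein 3 had -0.24 (SE 0.341, adjusted p = 0.995), and 0.40 within day 2 against 1 control array. Within day 3 it went the other way, as the 1 high dose array stood at -8.45 and the control arrays at -7.10 and -6.82. Estrogen receptor alpha, the receptor through which estrogens induce egg proteins in liver, had -0.06 (SE 0.121, adjusted p = 0.995). Alpha-amylase had -0.57, complement C3-S 0.18, cyclin B1 -0.08, CD18 type 2 0.02, cytochrome b -0.03 and cadherin 17 0.02. The value of alpha-amylase was -0.44 with scan day as a block (limma adjusted p = 0.948). Within days 2 and 3 it was -3.42 and 1.78, and these opposite signs rest on 1 control array on day 2 and 1 high dose array on day 3. limma called 0 of 9252 probes, with 340 at an unadjusted p under 0.05, where chance gives 463, and a smallest adjusted p of 0.137. The median SE was 0.190, and the median 95% interval reached 1.33-fold either way. Blocking on scan day gave 0 calls (577 at an unadjusted p under 0.05), and within days 2 and 3, with 1 control and 1 high dose array respectively, the counts were 0 and 0 (324 and 453). Median centring and the fit to all 28 arrays gave 1 call each, as did leaving out control array 1 or high dose array 2.

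In liver at the low dose, alpha-amylase lay below control, with mean log2 ratios of 4.43 ± 1.42 (SD) at the low dose and 7.27 ± 2.02 in control, but the difference of -2.84 (SE 0.984) did not pass (limma adjusted p = 0.83, and 0.124 adjusted over the list alone). With scan day as a block it was -2.71 (limma adjusted p = 0.579). Within day 2 it was -6.57 (limma adjusted p = 0.0205), against 1 control array that had the highest value of the 12 liver arrays, 9.79, so this value describes that array. Within day 3 it was -1.32 (limma adjusted p = 1.00), with 1 low dose array. CD18 type 2 was at 0.18 (SE 0.0976, adjusted p = 0.873), cytochrome b at -0.28 (SE 0.232, adjusted p = 0.887) and cadherin 17 at -0.18 (SE 0.156, adjusted p = 0.887). The value of cytochrome b leans on low dose array 3, which stood at 1.19, as the other low dose arrays lay between 2.06 and 2.21. None of the 9 named genes tested passed. The remaining 5 were zona pellucida glycoprotein 3 at -0.27, complement C3-S at 0.15, the taurine transporter at -0.13, estrogen receptor alpha at -0.08 and cyclin B1 at -0.04.

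Over all probes of liver at the low dose, limma called 0 of 9252, with 531 at an unadjusted p under 0.05 and a smallest adjusted p of 0.209. Scan day in the model gave 0 calls (783 at an unadjusted p under 0.05). Within day 2, against that 1 control array, there were 17 calls, all lower at the low dose, which describe the array, and within day 3, with 1 low dose array, there were 0 (482 and 186 at an unadjusted p under 0.05). The fit to all 28 arrays gave 2 calls, and so did leaving out control array 1 or control array 4.

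**Figure D4:**
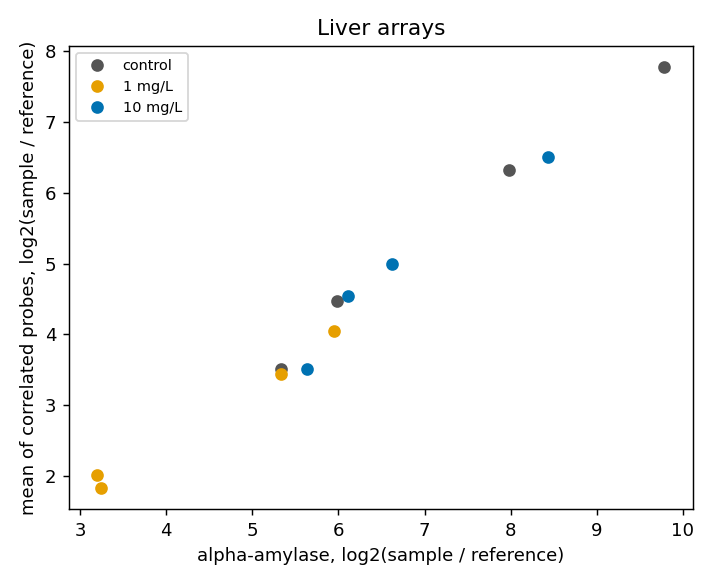
Each point is 1 of the 12 liver arrays, with the log2 ratio of alpha-amylase on the horizontal axis and the mean log2 ratio of the 25 probes that correlated with it on the vertical axis, coloured by dose. Alpha-amylase reached 9.79 and ranged 96.0-fold, and the group means were 7.27 in control, 4.43 at the low dose and 6.70 at the high dose.

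Between the doses in liver, 1 probe was higher at the high dose than at the low dose. EA_Pp_58199 (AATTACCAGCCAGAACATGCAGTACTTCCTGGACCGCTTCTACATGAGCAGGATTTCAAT), which the files do not pair with a gene name, differed by 1.49 (SE 0.172, limma adjusted p = 0.0166), with mean log2 ratios of 1.49 ± 0.31 (SD) at the high dose and 0.00 ± 0.12 at the low dose, and it was well above background on 4 and 2 of the 4 arrays. Its difference from control at the high dose was 1.21 (SE 0.172), which did not pass (limma adjusted p = 0.137). Alpha-amylase was at 2.27 for high minus low dose (SE 0.984, adjusted p = 1.00), and none of the 9 named genes passed. limma gave 350 of 9252 probes at an unadjusted p under 0.05. The call was kept with scan day as a block and lost with the replicate number as a block. The stricter filter on dim probes, which asks for signal well above background on every array of the fit, left this probe untested. Among other settings, the call was lost within day 2 with 2 arrays against 2, with the scanner's own ratios, with the authors' values and with alpha-amylase as a covariate. It was also lost on leaving out high dose array 1, 3 or 4, or low dose array 1, 3 or 4.

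The responses of liver and gill to the same dose were compared through their difference, liver minus gill. None of the 14 named genes tested passed at either dose. At the low dose alpha-amylase, which was not well above background on any gill array, did not pass (adjusted p = 1.00), and at the high dose the taurine transporter was at -0.49 (SE 0.299, adjusted p = 0.89) and zona pellucida glycoprotein 3 at -0.66 (SE 0.433, adjusted p = 0.916). limma called 0 of 13613 probes at the high dose, with 831 at an unadjusted p under 0.05 and a smallest adjusted p of 0.107, and 0 at the low dose, with 629 and 0.844. Blocked by scan day, the counts were 2 at the high dose and 0 at the low dose (1310 and 853 at an unadjusted p under 0.05). Within day 2 they were 1 and 19, and within day 3 they were 3 and 5, and each of these rests on groups of 1 array.

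The effects of both doses on all probes were set against each other within each tissue. In gill the log2 differences from control at the low and the high dose correlated at r = 0.492 across probes, and in liver at 0.525. Both doses share the same 4 controls, and simulated unchanged groups gave a mean of 0.499 (range 0.441 to 0.557) in gill and 0.501 (0.440 to 0.550) in liver. The covariance was 0.0358 in gill, where the simulations gave a mean of 0.0323, and 0.0529 in liver, where they gave 0.0467, both inside the simulated ranges of 0.0273 to 0.0387 and 0.0393 to 0.0572. With the controls split between the doses in all 6 ways, the mean correlation was 0.0474 in gill (-0.0391 to 0.155) and 0.0539 in liver (-0.125 to 0.138). With scan day as a block the correlations were 0.564 and 0.565, inside the ranges of unchanged groups simulated with that block (0.479 to 0.605 and 0.467 to 0.610). The covariances, 0.0461 in gill and 0.0623 in liver, lay above the highest simulated values of 0.0421 and 0.0612. Probes were simulated as independent of each other, and the blocked simulation was chosen after seeing the data. A shared effect of the doses was therefore not detectable without the block and is left open with it.

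The brain comparisons have 1 control array, so they rest on a spread taken from the other groups and cannot establish a difference in brain. A fit to the 4 brain arrays alone takes its spread from the 2 high dose arrays only. Its counts of calls at either dose therefore reflect how alike those 2 arrays are. At the high dose, 14 of 13607 probes passed under that assumption, 5 higher and 9 lower, and none of them carries a gene name in the files. EA_Pp_59014 was higher by 1.83 (SE 0.192, limma adjusted p = 1.81e-05) and EA_Pp_56882 by 1.69 (SE 0.137, limma adjusted p = 2.5e-07), while EA_Pp_50501 was at -2.88 (SE 0.372, limma adjusted p = 0.000427) and EA_Pp_53131 at -2.25 (SE 0.425, limma adjusted p = 0.0279). Of the 14 named genes tested, cytochrome b was nearest at 0.56 (SE 0.412, adjusted p = 1.00). The 2 high dose arrays correlated at 0.993, above any pair of gill or liver replicates, and whether they came from separate fish is not given in the sources used here. Averaged into 1 sample they gave 3 calls, and leaving out array 1 or array 2 gave 5 or 3. The stricter filter on dim probes gave 0 calls and the 4 brain arrays alone gave 988. The scan-day block gave 20. The balance of directions turned with the processing, as no background subtraction gave 33 calls with 21 higher, array weights 39 with 25 higher and the authors' values 19 with 14 higher, so no direction is claimed.

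In brain at the low dose, 1 array was set against 1 array, and the number of probes that passed under the same assumption, 46 of 13604 with 44 higher and 2 lower, is no evidence of an effect of dose. None of the 14 named genes passed, with follistatin nearest at -0.38. The low dose array lay above the control array by 5.65 for EA_Pp_52586, and EA_Pp_66057 was not well above background in control, while EA_Pp_70284 was at -1.89 and EA_Pp_68109 at -1.38. The brain low dose array carried gill signal, estimated at 17.3%, and 39 of the 44 higher probes were over 3 log2 units higher in gill than in brain, as were 1.30% of all probes tested. Without probes of that kind 3 calls were left, the stricter filter gave 15, the 4 brain arrays alone gave 2172, and scan day as a block gave 66.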

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

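All tests of the patterns in this part, and of the splits of the arrays, were chosen after the values had been seen. Of 78 groups of 4 arrays examined for an array far from the rest, 5 held one, where chance gives 3.9. The rule picks about 1 in 20 groups by chance.

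Pentraxin was at a log2 ratio of 4.76 on gill control array 3, and the other gill controls lay between -2.54 and -2.15. Lamin B1 was at 0.21 on gill low dose array 3, and the others of that group lay between 0.00 and 0.03. The taurine transporter was at 1.26 on liver low dose array 3, and the others lay between 0.07 and 0.23. Cytochrome b was at 1.19 on the same array, and the others lay between 2.06 and 2.21.

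The share of brain signal was 14.8% on gill control array 1, against -0.62% to 1.11% on the other gill controls, and the share of gill signal was 17.3% on the brain low dose array. A swap or wrong tissue label is argued against by the correlation of each array with its own tissue, which exceeded that with the other by at least 0.240, and a fault of the array or its background by liver-specific probes, of which at most 8.87% were well above background on either array. RNA of both tissues on 1 array may account for the pattern, since at least 98.1% of the probes specific to the other tissue were well above background on each. Whether tissue was mixed at dissection, in the RNA or during labelling was not tested.

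Alpha-amylase varied 96.0-fold between the 12 liver arrays, and 25 of 9171 probes correlated with it at r of at least 0.9, where 1000 permutations of the arrays gave at most 10. Scan day alone as the whole cause is argued against by a range of 6.59 log2 units within 1 day. Dose alone is argued against by a range of 4.45 within 1 dose group. The arrays at the ends of the range within 1 day differed in dose. Those at the ends of the range within 1 dose group differed in scan day. These ranges therefore cannot decide whether dose and scan day together account for the variation. A varying share of amylase-rich cells, such as exocrine pancreas, in the dissected liver is a candidate explanation: the 25 probes followed alpha-amylase with a median slope of 0.908, and 48% of them were not well above background on any gill or brain array, against 2.99% of all probes tested, but only 1 of 16 genes on the exocrine pancreas list was named on the array. For the difference between low dose and control, no test here separates dose from such a share. At the low dose the mean of the 25 probes lay below control by a log2 difference of -2.69. These probes were picked for following alpha-amylase on the same arrays, so they repeat its difference of -2.84. The 2-sided exact permutation p was 0.0857 for alpha-amylase (0.129 adjusted over 3 comparisons) and 0.0571 for the 25 probes (0.0857 adjusted). With 4 arrays against 4 no p under 0.0286 is possible.

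In gill 63 probes and in liver 84 stood at 2 separate levels among the 12 arrays, with a gap of at least 1 log2 unit, and 13 probes did so in both tissues, where independent lists give 0.246 (Fisher's exact p = 1.68e-19). That expectation counts all 21495 probes, dim ones included, and treats probes as independent. It may therefore be too low and the p too small. Dose alone and scan day alone are argued against as the whole cause, since in 26 of 26 probe and tissue cases both levels occurred inside 1 dose group, and in 26 of 26 on 1 scan day. For most cases the dose part follows from the number of arrays at each level, which could not be divided along whole dose groups. Where the upper level held 4 or 8 arrays it could, and there too both levels occurred inside 1 dose group. Part of the scan-day cases have the same limit. Scan day may still contribute, since in 3 of the 26 cases the level went with scan day at an unadjusted Fisher exact p under 0.05. The level went with dose in 0 cases at that p, but this count cannot be set against the 3. In dose groups of equal size, a level held by only 2 or 3 arrays cannot reach such a p. Many of the cases were of that kind, and the scan days were of unequal size. A difference between individual fish that both tissues carry, such as a genetic variant under the probe or in the expression of the gene, may account for the 13 probes and was not tested on genotypes. If the levels belong to fish, gill and liver arrays of the same number did not all come from the same fish, since their levels matched in 94 of 156 cases, against 96.8 expected by permutation (permutation p = 0.676), and 25 of 39 group counts differed between the tissues.

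For gill against liver in control fish, 1 of the 35 splits of the 8 arrays, the real one, gave as many calls as the real 5381, and the highest other split gave 6, so chance could be excluded. For gill at the high dose against control the real count was 0 calls, which 35 of 35 splits reach by construction (highest other 1), so the count of calls decides nothing about chance. Its 1297 probes at an unadjusted p under 0.05 were reached by 1 of 35 splits, the real one, and the highest other gave 1041. The count of 1297 was picked as the highest of 6 dose comparisons, and 35 splits are too few for a share under 0.05 after that choice. For gill high against low dose, the 1015 probes at an unadjusted p under 0.05 were reached by 4 of 35 splits, and the highest other gave 1413.

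The real count of 1 for liver high against low dose was reached by 7 of 35 splits (highest other 1), so chance could not be excluded. The other comparisons had a real count of 0 calls, which every split reaches, so their splits decide nothing about chance: 35 of 35 for gill low dose against control (highest other 0), gill high against low dose (3), liver high dose against control (1) and liver low dose against control (18), and 100 of 100 drawn splits for the differences between tissues in the response, with a highest other of 9 at the high dose and 23 at the low dose. The split with 18 calls set liver control arrays 1 and 3 and low dose arrays 1 and 3 against the rest, and such a count beside a real 0 points to a structure of the samples, which was not tested; it did not follow the number in general, since the other splits that kept arrays of the same number together, 1 and 2 or 1 and 4, gave 0 calls each.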

How the results depend on the processing

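Scan-day fits, fits without doubted arrays or probes, averaged brain arrays and the alpha-amylase covariate were chosen after seeing the data. Of 311 alternative values of 13 summary results, 229 were the same, 22 weaker, 52 stronger, 8 moved and 0 reversed. A count was the same if it equalled the main count, 0 included, or lay within 1.5 times of it, whatever its balance of directions. Only a dose correlation could be labelled reversed, so for the counts 0 reversed was fixed in advance. A dose correlation was the same if it differed from the main one by at most 1 SD of the values with 1 array left out. Of 1006 for named genes, 943 were the same, 17 weaker, 1 stronger and 45 moved. A called value was the same if it kept its sign and its call. A value not called was the same if it stayed uncalled and within 1 SD of arrays within groups, whatever its sign. Of the called values 0 changed sign, but 78 of the values not called did, in 25 results, and some of these count as the same. Weak signal over background limits the count of testable probes, and the stricter filter tests fewer. Unless the construction shows it, the cause was not tested.

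Calls by setting were as follows. No background subtraction gave 1 in gill high and 1 in gill low against control and 33 in brain high. The scanner's ratios gave 1 in gill high, 0 in liver high against low, 4 in brain high and 77 in brain low. Median centring, which moved the median of all probes by -0.20 in gill high and 0.29 in gill against liver, gave 1 in liver high, 2 in liver high against low, 24 in brain high and 1 in the high dose difference between tissues. The authors' values gave 0 in liver high against low. No filter gave 31 in brain high. The stricter filter gave 10 in gill high, 1 in gill high against low, 0 in liver high against low, 0 in brain high, 15 in brain low and 2638 in gill against liver, 2489 of them shared. Array weights gave 3 in gill high against low, 4 in liver high against low, 39 in brain high and 73 in brain low. All 28 arrays gave 53 in gill high, 2 in gill high against low, 1 in liver high, 2 in liver low and 5 in liver high against low, and the 4 brain arrays alone gave 988 in brain high and 2172 in brain low.

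Scan day as a block gave 2 in the high dose difference between tissues and dose correlations of 0.564 in gill and 0.565 in liver. Within day 2 there were 17 in liver low, 0 in liver high against low, 1935 in gill against liver, 1 and 19 in the high and low dose differences between tissues, and within day 3 there were 0 in liver high against low, where 1 array was set against 1, and 3 and 5 in those differences. All of these but liver high against low on day 2 involve a group of 1 array. Without both doubted gill arrays there were 1 in gill high, 3 in gill high against low and 1 in the high dose difference. Brain low without gill-high probes gave 3, averaged brain arrays 3, and the covariate 0 in liver high against low.

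Leaving out 1 array gave 0 to 1 calls in gill high, 0 to 1 in gill low, 0 to 2 in gill high against low, 0 to 1 in liver high, 0 to 2 in liver low, 0 to 2 in liver high against low, 3 to 5 in brain high, 4844 to 5055 in gill against liver, 0 to 1 and 0 to 2 in the high and low dose differences between tissues, and dose correlations of 0.385 to 0.585 in gill and 0.409 to 0.656 in liver. Where 1 brain high array was left, it was assumed to vary like the other groups.

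The replicate numbers were not taken to pair the samples, because in no tissue did every same-numbered pair correlate over 0.1. Deviations of same-numbered arrays did so in 1 of 12 pairs in gill, 7 of 12 in liver and 4 of 12 between gill and liver, and an array correlated best with its own number in 3, 15 and 8 of 24 cases. In liver the mean correlation was 0.117 for the same number and -0.0386 for other numbers, a hint of pairing from the data and not from the design. Most same-numbered liver pairs also shared a scan day, and liver pairs averaged 0.0769 on the same day and -0.0379 on different days. Liver control array 3 was scanned on another day than the high and low dose arrays of its number, and correlated with them at 0.0344 and 0.242. Liver pairs of different numbers on the same day lay between -0.0957 and 0.108. The high dose value lies inside that range and the low dose value above it. These few pairs do not settle whether replicate number or scan day is behind the correlations. All 4 liver pairs of control and low dose lay over 0.1 (0.171 to 0.325), and those of the high dose did not all. With the replicate number as a block, the 1 call of liver high against low was lost (0 calls), and there were 0 in gill high, 11 in brain high, 44 in brain low and 5593 in gill against liver, and liver low had 0 (687 at an unadjusted p under 0.05) with alpha-amylase at an adjusted p of 0.555. By pairs alpha-amylase and its 25 probes were lower at the low dose in 4 of 4, with a sign-flip exact p of 0.125, the smallest that 4 pairs can give, so that test cannot pass; it was chosen after seeing the data. A slide block was not run, as each slide held 1 array, and the planned list tests were not run for lack of named genes.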

Other observations

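The sets of probes and the tests in this part were made from these arrays after the data were seen, and they describe them. Probes over 3 log2 units higher in 1 tissue than in both others were taken as enriched in that tissue. The 61 gill-enriched probes tested had median log2 differences from control of 0.30 at the high dose, with 46 higher, and 0.31 at the low dose, with 50 higher. camera with a preset correlation of 0.01 gave adjusted p values of 0.000252 and 8.33e-08, and with an estimated correlation of 0.234 the adjusted p was 0.31 and 0.522, so neither call held. Other sets were called at the preset correlation too, such as liver-enriched (median 0.26) and reference-enriched probes (0.35) at the high dose in gill, and with estimated correlations none held there (adjusted p = 0.31). Without gill control array 1 and gill high dose array 2 the gill-enriched probes stood at 0.32 and 0.24, still called at the preset correlation (camera adjusted p = 0.000233 and 6.38e-05). At the high dose the liver-enriched probes had a median of 0.06, no longer called (camera adjusted p = 0.159), and the reference-enriched probes 0.13 (camera adjusted p = 0.0211), at that correlation. An estimated correlation was not used without these arrays, so whether those calls hold with it is open. The 153 brain-enriched probes had medians of -0.31 and -0.41, called lower at the preset correlation (camera adjusted p = 0.000252 and 1.46e-12). Without gill control array 1 and gill high dose array 2, 137 such probes were tested and the medians were -0.03 and 0.06. At the preset correlation the high dose was then not called (camera adjusted p = 0.539), and the low dose was called the other way, as higher (camera adjusted p = 0.00153). The 25 probes that followed alpha-amylase in liver had a median of -2.75 at the low dose, with 0 of 25 higher, with an adjusted p of 9.01e-25 at the preset correlation and 0.189 at an estimated correlation of 0.915. Of the calls at the preset correlation that bear on the dose groups, 1 held with an estimated correlation, the gill-enriched probes in the brain low dose array (median 2.49, 61 of 61 higher, adjusted p = 1.54e-07), which compares 1 array with 1 array.

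Pentraxin was high on single arrays of different groups. Its log2 ratio reached 4.76 in 1 gill control, 2.44 in 1 liver control and 2.16 in 1 liver low dose sample, and its range was 189-fold over gill arrays.

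Of 1618 probes whose names end in minus, 23.7% of probe and array values were well above background in Cy5, against 46.3% for the 19877 others.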
